A study of Mus musculus with 8 samples.

How the data were processed

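The series measured mRNA in follicular regulatory T (TFR) cells sorted from mouse spleen. Per the labels, CD4+ T cells were enriched with a column kit from mice that had received 2 oral challenges with peanut and cholera toxin, 36 days after challenge. TFR cells were then sorted by flow cytometry as Foxp3-YFP+ CXCR5+ PD1+ cells. The labels name 4 WT libraries and 4 libraries from mice with a floxed Blimp1 gene and Foxp3-cre, called Blimp1-flox here. They do not state whether the WT mice carried Foxp3-cre, whether 1 or both alleles were floxed, or whether the libraries of a group came from separate mice. The p-values therefore measure the spread between these libraries, part of which may be technical.

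RNA was extracted with a micro column kit and libraries were made with the KAPA mRNA HyperPrep kit, per the labels. Reads were aligned with STAR 2.5.2b to mm10 and counted per gene with featureCounts of Subread 1.5.1, per the submitters' processing notes. The deposited values are raw counts per gene, without normalization, for 24421 genes. The deposited table also gives the summed exon length of each gene in bases, a measurement of another kind that was used only for a check of gene length. The gene annotation and the strand setting of the counting were not given in the sources used here. Reads in exons that 2 genes share can be dropped or assigned to either gene, so genes with overlapping exons are named as uncertain. No gene of the mitochondrial genome has a row, 1 antigen receptor segment gene has a row, and 10 haemoglobin genes are listed at 0 in every library, so shares of those classes could not be compared.

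Library totals ranged from 16425538 to 27595939 counts. Genes were kept with filterByExpr of edgeR, which left 12363 genes, and libraries were scaled by TMM, with factors from 0.976 to 1.02. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust estimation and a model holding genotype alone. The p-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Every adjusted p of a single gene comes from this test unless another is named. Log2 fold changes are Blimp1-flox relative to WT, and their standard errors were derived from the F statistic. Levels are TMM-scaled CPM (counts scaled to a common library total), computed here from the deposited counts, as mean ± SD over 4 libraries. The biological coefficient of variation was 0.192.

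A total of 31 gene lists holding 607 genes were fixed before the data were examined. They cover Treg core, effector Treg, TFH and follicular, naive and central T, TH1, TH2, TH17, cytotoxic granule, inhibitory receptor, Blimp1-repressed, migration and adhesion, cytokine, cytokine receptor and JAK-STAT, TGF-beta, NF-kB and TNF receptor, cell cycle, interferon-stimulated, apoptosis, glycolysis, oxidative phosphorylation, cholesterol, unfolded protein response, immediate early, heat shock and ribosomal protein genes. They also cover B cell, plasma cell, myeloid and dendritic, CD8 and NK, erythroid and platelet, and sex-linked genes. The 29 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with the preset correlation between genes of 0.01. The CD8 and NK list and the sex-linked list had too few tested genes. Camera with an estimated correlation and fry were run as alternatives. Members were also counted with p-values adjusted over the list alone.

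The rule for naming genes was also fixed before the data were examined. It took 12 genes whatever their result, the 10 called genes with the highest and the 10 with the lowest log2 fold change, and up to 4 called members of each list. The groups of the highest and lowest genes had to have a mean log2 CPM of at least 1 and no overlap between the genotypes, and gene models without a symbol of their own, receptor segments and sex-linked genes were left out. Genes named outside this rule are said to have been chosen after their values were seen. The values of some single list members are not reported here.

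Library composition was compared with exact two-sided permutation tests over the 70 assignments of 8 libraries, which can give no p below 0.0286. Alternatives fixed before the data were examined were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom with quality weights, no filter and a stricter filter, a replicate block, each library left out in turn, other thresholds, other list tests and removal of receptor segment, mitochondrial and haemoglobin genes. Alternatives chosen after the data were seen left out 2 libraries together, added a B cell score, added a batch term, placed 1 library in the other batch, and removed a gene length trend. The gene test was tested on simulated data for Blimp1-flox against WT with 12230 genes and 200 changed genes in each of 5 runs. It recovered 40.2% of genes changed 1.5-fold, 73.5% of those changed 2-fold and 91.7% of those changed 4-fold. Of its calls 7.11% were false, a share above the 0.05 at which the adjusted p aims.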

Results

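Poly(A) RNA of sorted splenic TFR cells was sequenced in 4 WT and 4 Blimp1-flox libraries, taken 36 days after 2 oral challenges with peanut and the adjuvant cholera toxin. TFR cells are Foxp3-expressing T cells of the B cell follicle that restrain germinal centre responses. The comparison addressed how Blimp1, a transcriptional repressor encoded by Prdm1, shapes gene expression in these cells. The WT libraries held 25383287, 23150496, 22788722 and 26279365 counts, and the Blimp1-flox libraries held 16425538, 24199546, 27595939 and 23498633 counts.

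Prdm1 itself fell by 2.14 ± 0.31 (SE) on the log2 scale in Blimp1-flox cells, from 51.8 ± 19.2 CPM to 11.8 ± 4.02 CPM (SD, n = 4; edgeR quasi-likelihood adjusted p = 0.0203). The WT libraries held 39.1, 31.8, 65.1 and 71.0 CPM of Prdm1 and the Blimp1-flox libraries 13.4, 7.53, 9.60 and 16.6 CPM, so every library lay on the side its label gives. Prdm1 lies on chromosome 10 from 44437174 to 44458748 in mm10. Which of its exons are floxed was not given in the sources used here, so the counts may include exons that the deletion leaves. Without Blimp1-flox 1 the adjusted p of Prdm1 was 0.103, with a log2 fold change of -2.21. With no filter on low counts it was 0.0502.

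Of 12363 genes tested, 62 changed, 32 higher and 30 lower in Blimp1-flox cells. The transcript of the anti-inflammatory cytokine IL-10 (Il10) fell 7.06-fold, from 75.4 ± 15.8 to 10.6 ± 5.18 CPM (SD, n = 4; edgeR adjusted p = 0.00502). The IL-23 receptor gene Il23r rose 11.7-fold, from 0.613 ± 0.161 to 7.28 ± 3.42 CPM (SD, n = 4; edgeR adjusted p = 0.00112). All 62 genes had no overlap between the groups, as did 8.47% of all tested genes, against 2.86% by chance. The count was 127 without WT 1, 27 without WT 2, 20 without Blimp1-flox 1, 94 without Blimp1-flox 3 and 23 without Blimp1-flox 4. On the first principal component of log2 CPM WT 4 stood at -51.8 and the other WT libraries at -19.7 to -1.77. The Blimp1-flox libraries stood at 9.73 to 30.9, so this component divided the genotypes. On the second Blimp1-flox 3 stood at -50.8 and all other libraries at -1.62 to 12.0. Without both libraries 157 genes were called, 55 of them among the 62. DESeq2 called 457 genes and limma-voom with quality weights 494, among them 62 and 61 of the 62. With a B cell score as a covariate edgeR called 0 genes, with 684 at an unadjusted p under 0.05. All 62 genes kept their sign in that fit. The score shared 62.6% of its variance with genotype, so calls lost with it do not tell B cell RNA from genotype.

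**Figure D1:**
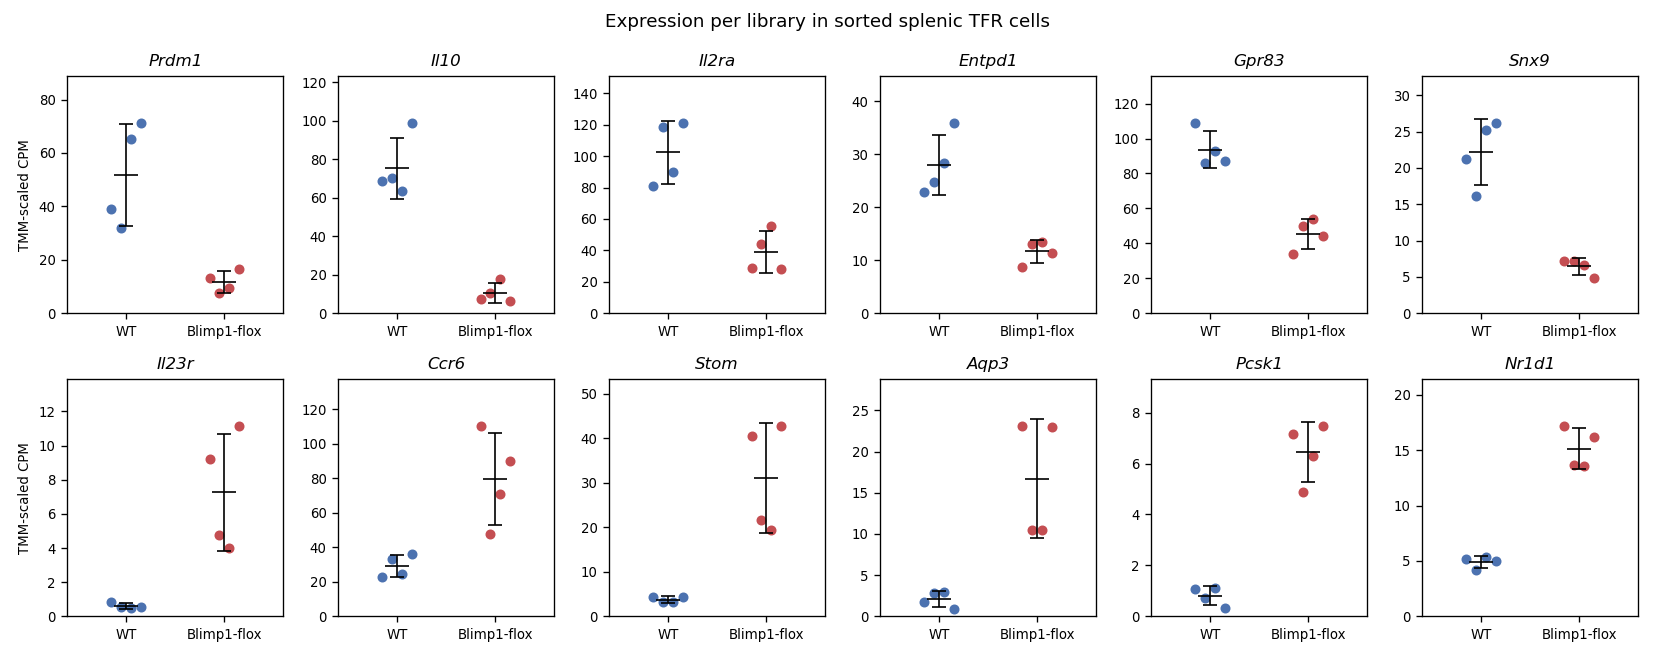
Expression of 12 genes, 1 panel per gene, in TMM-scaled CPM (vertical axis) for WT (blue) and Blimp1-flox (red). Points are single libraries, long ticks are means and bars are SD over 4 libraries. In each panel the libraries of the genotypes do not overlap, as for Prdm1, with means of 51.8 and 11.8 CPM.

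Among the transcripts with the highest fold changes in Blimp1-flox cells was Mmp25, a membrane-anchored matrix metalloproteinase. It had 1 count over the WT libraries, in WT 1, and 387 over the Blimp1-flox libraries. The ratio of the pooled levels was 412, with a 95% counting interval from 73.5 to 16308 that leaves out the spread between libraries. The log2 fold change of Mmp25 was 8.15 ± 0.75 (SE; edgeR adjusted p = 4.9e-04). Ltb4r1, the high-affinity receptor of leukotriene B4, rose by a log2 fold change of 4.98 ± 0.73 (SE). Stom, which encodes the membrane protein stomatin, rose 8.18-fold, from 3.78 ± 0.697 to 31.1 ± 12.3 CPM (SD, n = 4; edgeR adjusted p = 5.5e-04). Aqp3, a water and glycerol channel, rose 7.92-fold and Pcsk1, a prohormone convertase, 7.91-fold. Sh3rf2 rose 5.35-fold, Lgals3, which encodes galectin-3, 4.01-fold, and Nr1d1, the circadian repressor REV-ERB alpha, 3.07-fold. Sdc1, the proteoglycan syndecan-1, rose 3.66-fold from a low level of 1.47 ± 0.546 CPM in WT (SD, n = 4). Calls on Ltb4r1 were lost without WT 2 or WT 3 and on Sh3rf2 without Blimp1-flox 1 or 4, with adjusted p up to 0.104. The call on Ltb4r1 was also lost in limma-voom with quality weights (5.45, adjusted p = 0.0943). The call on Sdc1 was lost without WT 2, WT 3, Blimp1-flox 1, 2 or 4, with adjusted p up to 0.134.

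Among the lowest transcripts besides Il10 and Prdm1, Neb, which encodes the giant thin-filament protein nebulin, fell by 3.94 ± 0.55 (SE) on the log2 scale. WT 4 held 45.7 CPM of Neb and the other WT libraries 14.3 to 16.5 CPM, and 1 exon of Neb overlaps an antisense gene. Snx9, a sorting nexin of endocytosis, fell 3.44-fold, from 22.2 ± 4.52 to 6.46 ± 1.14 CPM (SD, n = 4; edgeR adjusted p = 0.00112). Tacc2 fell 3.04-fold, Ppp3ca, the catalytic subunit of calcineurin, 2.51-fold, and Gbp7, an interferon-inducible GTPase, 2.11-fold. Without WT 4 the log2 fold change of Neb was -3.35, and with no filter on low counts its call was lost (adjusted p = 0.0559). Calls on Neb were also lost without Blimp1-flox 3 or 4, and on Tacc2 without WT 2, Blimp1-flox 1, 2 or 4, with adjusted p up to 0.113. Calls on Ppp3ca were lost without WT 2, WT 3, Blimp1-flox 1, 2 or 4, and on Gbp7 without WT 2 or any 1 Blimp1-flox library, with adjusted p up to 0.172. The call on Ppp3ca was also lost after removal of a gene length trend (adjusted p = 0.0598). With a B cell score as a covariate the log2 fold change of Ppp3ca went from -1.33 to -0.57. That of Gbp7 went from -1.08 to -0.58, and 20 of 29 called named genes had a smaller fold in that fit.

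Genes of the Treg core list fell in Blimp1-flox cells. Of 18 tested members 4 fell, none rose and 14 did not pass, and 7 fell with p adjusted over the list alone (camera adjusted p = 1.5e-06; adjusted p = 0.0426 with an estimated correlation). Il2ra, the high-affinity IL-2 receptor chain, fell 2.62-fold, from 103 ± 20.0 to 39.0 ± 13.2 CPM (SD, n = 4; edgeR adjusted p = 0.0311). The ectonucleotidase gene Entpd1 (CD39) fell 2.38-fold, Gpr83 2.05-fold and the cytokine signalling inhibitor Socs2 3.19-fold. The call on Il2ra was lost without WT 2, Blimp1-flox 1, 2 or 4 (adjusted p up to 0.105), and on Socs2 in 6 of 8 such fits, those without WT 2, 3 or 4 or Blimp1-flox 1, 2 or 4 (up to 0.170). The log2 fold changes of Il2ra, Entpd1, Gpr83 and Socs2 were -1.39, -1.25, -1.04 and -1.67. With a B cell score as a covariate they were -1.24, -0.85, -1.19 and -0.83. Foxp3, the lineage factor of regulatory T cells, had a log2 fold change of -0.40 ± 0.13 (SE), which did not pass over all genes (edgeR adjusted p = 0.176). It was among the 7 members that fell with p adjusted over the list alone, and it passed in limma-voom with quality weights (-0.43, adjusted p = 0.0321; over all alternatives 0.0321 to 0.572). Foxp3 exons overlap 2 other genes, Ccdc22 and Ppp1r3fos, so its counts are uncertain. Ctla4 had a log2 fold change of -0.23 and did not pass either (edgeR adjusted p = 0.372).

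The effector Treg list did not pass as a whole (camera adjusted p = 0.191). Il10 was its 1 called member of 31, and with p adjusted over the list alone 5 members fell and 2 rose. The inhibitory receptor list (camera adjusted p = 0.249) held 1 called gene, Entpd1, among 18. The cytokine list (camera adjusted p = 0.191) held 1, Il10, among 20, and it passed with fry (adjusted p = 0.0358), which does not compare a list with other genes.

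TH17 genes rose. Of 13 tested members 3 were higher, none was lower and 10 did not pass, and 8 rose with p adjusted over the list alone (camera adjusted p = 1.2e-06; adjusted p = 0.0614 with an estimated correlation). Besides Il23r and Ltb4r1, the chemokine receptor gene Ccr6 rose 2.73-fold, from 29.1 ± 6.39 to 79.6 ± 26.5 CPM (SD, n = 4; edgeR adjusted p = 0.0334). The call on Ccr6 was lost without WT 2, WT 3, Blimp1-flox 1 or 4, with adjusted p up to 0.109, and with no filter on low counts (adjusted p = 0.0604).

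TH1 genes fell as a list, although no single member passed over all genes in edgeR. With p adjusted over the list alone, 5 of 15 fell and 1 rose (camera adjusted p = 0.0168; adjusted p = 0.287 with an estimated correlation). With a B cell score as a covariate the TH1 list no longer passed (adjusted p = 0.564). Tbx21, the TH1 lineage factor T-bet, had a log2 fold change of -0.66 ± 0.19 (SE; edgeR adjusted p = 0.153). The Tbx21 log2 fold change passed in DESeq2 (-0.66, adjusted p = 0.0421) and in limma-voom with quality weights (-0.73, adjusted p = 0.0264), and over all alternatives its adjusted p ran from 0.0264 to 0.929. In the cytotoxic granule list 1 of 13 members, Nkg7, fell 2.05-fold (camera adjusted p = 0.0269; adjusted p = 0.329 with an estimated correlation). This list no longer passed without WT 3 (adjusted p = 0.0994), with the stricter filter (0.0974), with a B cell score (0.420), or without WT 4 and Blimp1-flox 3 (0.146), where its median log2 fold change was 2.6e-04. Nor did it pass with the level of pancreas transcripts as a batch term (0.0576, and 0.0734 with Blimp1-flox 1 in the high batch). The call on Nkg7 was lost in 6 of 8 fits, those without WT 2, 3 or 4 or Blimp1-flox 1, 2 or 4 (adjusted p up to 0.126), and with scaling by library totals only (0.0545). The TH2 list did not pass (camera adjusted p = 0.554), and 1 of 15 members, the IL-4 receptor gene Il4ra, fell 1.51-fold. The call on Il4ra was lost without WT 2, Blimp1-flox 1 or 4, with adjusted p up to 0.1004. Gata3 and Il4 had log2 fold changes of -0.13 and 0.40, and neither passed (edgeR adjusted p = 0.619 and 0.403).

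Follicular genes shifted upward together by a small amount. None of 31 TFH and follicular members passed singly, and 28 had a positive log2 fold change with a median of 0.21 (camera adjusted p = 4.5e-05; adjusted p = 0.290 with an estimated correlation). Bcl6, the lineage factor of follicular T cells and a known target of Blimp1, had a log2 fold change of 0.22 (edgeR adjusted p = 0.411). Cxcr5, Pdcd1 and Icos had log2 fold changes of 0.16, 0.30 and 0.12, and none passed. CXCR5 and PD1 were part of the sorting gate. With a B cell score as a covariate the follicular list no longer passed (adjusted p = 0.668), and Cxcr5 had a log2 fold change of -0.0501. The list of genes described as repressed by Blimp1 did not pass (camera adjusted p = 0.559), with 9 positive and 10 negative fold changes, and Ccr6 was its 1 called member. The naive and central T list did not pass (camera adjusted p = 0.315), and it passed downward without Blimp1-flox 3 (adjusted p = 0.0333).

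In the migration and adhesion list 2 of 30 members rose, Ccr6 and Gpr15, a homing receptor of the large intestine (camera adjusted p = 0.554 for the list). Gpr15 rose 2.95-fold, from 12.8 ± 5.05 to 37.9 ± 7.18 CPM (SD, n = 4; edgeR adjusted p = 0.0203), and its call was lost without WT 3, Blimp1-flox 1 or 4 (adjusted p up to 0.1005). Of 35 cytokine receptor and JAK-STAT genes, 25 had a negative and 10 a positive log2 fold change. With p adjusted over the list alone 6 fell and 3 rose. Over all genes Il2ra, Il4ra and Socs2 were lower, and the list as a whole fell (camera adjusted p = 0.0264, and 0.290 with an estimated correlation). That call was lost without WT 2 (adjusted p = 0.0857), WT 3 (0.0604) or Blimp1-flox 1 (0.0716), after removal of a gene length trend (0.0510), and with a pancreas batch term that placed Blimp1-flox 1 in the high batch (0.0521).

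Interferon-stimulated genes were lower in Blimp1-flox cells. All 33 had a negative log2 fold change, 2 fell over all genes and 18 fell with p adjusted over the list alone (camera adjusted p = 9.6e-12; adjusted p = 0.287 with an estimated correlation). Ifit1, an antiviral effector, fell 2.05-fold, and the transcription factor gene Irf1 fell 1.41-fold, from 622 ± 5.49 to 441 ± 46.3 CPM (SD, n = 4; edgeR adjusted p = 0.0339). The call on Ifit1 was lost without Blimp1-flox 1 and on Irf1 without WT 2, WT 3, Blimp1-flox 1, 2 or 4, with adjusted p up to 0.170. B cell transcripts were also lower in Blimp1-flox as a list (median -3.07, and -1.87 without WT 4; camera adjusted p = 1.3e-11; adjusted p = 0.311 with an estimated correlation), while their sum did not pass an exact two-sided permutation test (p = 0.114). With a B cell score as a covariate the interferon-stimulated list no longer passed (adjusted p = 0.0643). NF-kB and TNF receptor genes fell as a list with none of 22 called singly (camera adjusted p = 2.8e-04; adjusted p = 0.0614 with an estimated correlation).

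Immediate early genes, which respond to antigen receptor signals and to cell handling, fell as a list with none of 26 called singly (camera adjusted p = 0.00115; adjusted p = 0.311 with an estimated correlation). Heat shock genes fell likewise, with none of 15 called (camera adjusted p = 0.00214; adjusted p = 0.397 with an estimated correlation). Without WT 1 neither list passed (adjusted p = 0.0532 and 0.113). The TGF-beta signalling, apoptosis and survival, and unfolded protein response lists did not pass (camera adjusted p = 0.280, 0.249 and 0.449). The TGF-beta list passed downward with a B cell score as a covariate (adjusted p = 0.0188, median -0.34). Cdkn1a, the cell cycle inhibitor p21 and the 1 called member of the apoptosis list, fell 1.97-fold. Its call was lost in 6 of 8 fits, those without WT 1 or 3 or any 1 Blimp1-flox library, with adjusted p up to 0.182.

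Cell cycle genes rose as a list. The mitotic cyclin gene Ccnb1 was the 1 called member of 38 and rose 1.98-fold, and 10 rose with p adjusted over the list alone (camera adjusted p = 1.5e-06; adjusted p = 0.463 with an estimated correlation). The call on Ccnb1 was lost in 6 of 8 fits, those without WT 1, 2 or 3 or Blimp1-flox 1, 3 or 4, with adjusted p up to 0.150. Glycolysis genes had a median log2 fold change of 0.41 with 17 of 18 positive (camera adjusted p = 3.7e-05; adjusted p = 0.379 with an estimated correlation). With p adjusted over the list alone 3 glycolysis genes rose and 1 fell, and with a B cell score as a covariate the list no longer passed (adjusted p = 0.324). Oxidative phosphorylation genes had a median of 0.21 with 28 of 30 positive (camera adjusted p = 1.2e-06; adjusted p = 0.416 with an estimated correlation). Ribosomal protein genes had a median of 0.14 with 36 of 37 positive (camera adjusted p = 5.9e-04; adjusted p = 0.625 with an estimated correlation). The ribosomal call was lost without WT 2 (adjusted p = 0.0966) or Blimp1-flox 1 (0.0592), and after removal of a gene length trend (0.192). The cholesterol list did not pass (camera adjusted p = 0.315).

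**Figure D2:**
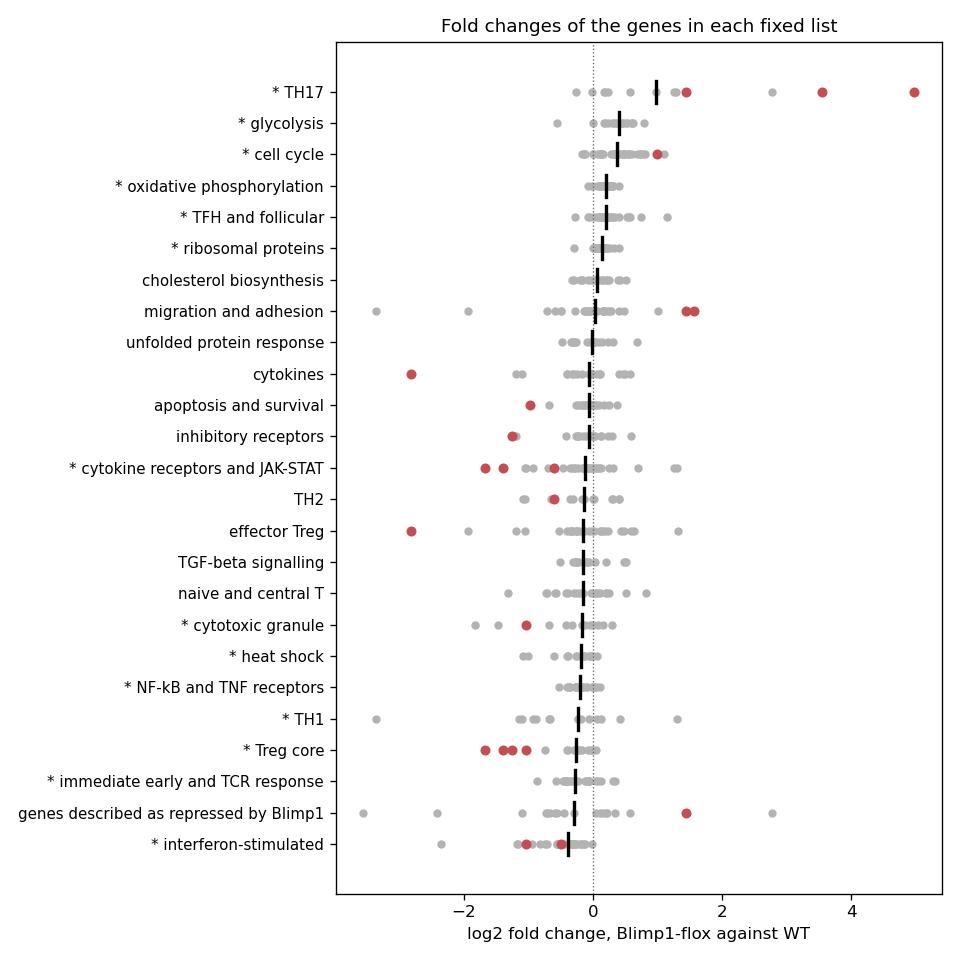
Log2 fold change of Blimp1-flox against WT (horizontal axis) for the tested genes of 25 fixed lists, 1 row per list. Red points are genes with an edgeR adjusted p under 0.05, grey points the others, black bars list medians, and asterisks lists with a camera adjusted p under 0.05. The TH17 list has the highest median, 0.98, and the interferon-stimulated list the lowest, -0.38.

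Genes of the lists for other cell types had counts in the libraries. Some are shared with T cell lists, such as Pou2af1 of the plasma cell list and Eomes of the CD8 and NK list. Their sums therefore do not by themselves show RNA of such cells. None of 21 B cell genes passed singly, and 16 fell with p adjusted over the list alone (camera adjusted p = 1.3e-11; adjusted p = 0.311 with an estimated correlation). Cd79a, a signalling chain of the B cell receptor chosen after its values were seen, held 11.1, 8.73, 28.1 and 122 CPM in WT and 3.47, 4.28, 4.57 and 2.51 CPM in Blimp1-flox. Of the 21 genes, 20 were highest in WT 4 and 12 were higher in all WT than in all Blimp1-flox libraries. Without WT 4 the median of the list was -1.87, against -3.07 with all libraries. The difference in summed B cell transcripts did not pass an exact two-sided permutation test (1332 ± 1055 against 632 ± 60.4 CPM, SD, n = 4; p = 0.114, adjusted 0.381). Summed plasma cell transcripts were 365 ± 19.1 CPM in WT and 472 ± 49.2 CPM in Blimp1-flox, and summed CD8 and NK transcripts 42.0 ± 5.06 and 52.0 ± 2.05 CPM (SD, n = 4). For both the exact permutation p was 0.0286, the smallest possible, and 0.143 after adjustment, so neither passed. The plasma cell list passed upward with Sdc1 as its 1 called member of 9 (camera adjusted p = 0.0225; adjusted p = 0.311 with an estimated correlation). It no longer passed without Blimp1-flox 1 (adjusted p = 0.0592) or Blimp1-flox 2 (0.0653). The myeloid and erythroid lists did not pass (camera adjusted p = 0.315 and 0.705), and the myeloid list passed upward without Blimp1-flox 3 (adjusted p = 0.00352), without WT 4 and Blimp1-flox 3 (7.2e-04) and with a B cell score as a covariate (0.0102).

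**Figure D3:**
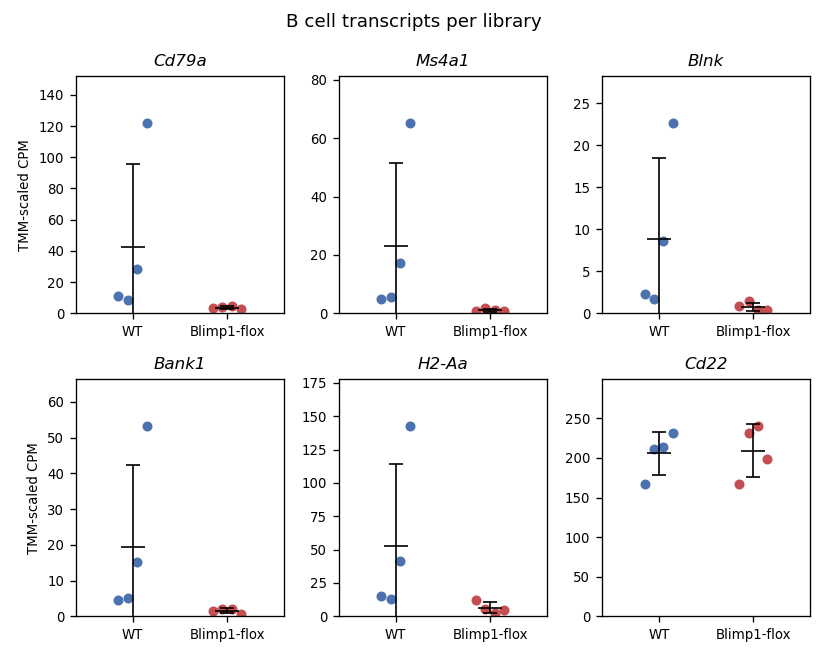
Expression of 6 genes of the B cell list, 1 panel per gene, in TMM-scaled CPM (vertical axis) for WT (blue) and Blimp1-flox (red). Points are single libraries, long ticks are means and bars are SD over 4 libraries. WT 4 is the high point of Cd79a, at 122 CPM, while Cd22 overlaps between the genotypes.

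Libraries of both genotypes also differed in transcripts of exocrine pancreas, an organ adjoining the spleen. The genes were listed after the data were seen, and Cela1 and Prss2, which had counts in every library, were left out of the sum. Over the other 24 genes the level was 34.2 CPM in WT 2, 21.3 in WT 4, 47.3 in Blimp1-flox 2 and 45.9 in Blimp1-flox 3. It was 0.473 CPM in WT 1, 1.10 in WT 3, 7.06 in Blimp1-flox 1 and 0.851 in Blimp1-flox 4. Taken as 2 batches divided at 10 CPM, a level chosen after the values were seen, each batch held 2 libraries of each genotype. With Cela1 and Prss2 included the sums were 32.7, 74.9, 35.5 and 53.0 CPM in WT 1 to 4 and 90.4, 112, 96.0 and 52.4 CPM in Blimp1-flox 1 to 4, which do not divide the libraries in this way. Within the high and the low batch the log2 fold change of Prdm1 was -2.59 and -1.80, that of Il10 -2.57 and -3.27, and that of Il23r 2.96 and 3.91. Other named genes differed more between the batches, with Ccr6 at 0.78 and 2.07, Gpr15 at 0.94 and 2.29, and Ltb4r1 at 3.24 and 5.88. Neb stood at -5.18 and -2.80, and Il4, which was not called, at -0.29 and 1.08. These differences were not tested. With 2 libraries of each genotype edgeR called 0 genes in the high batch and 312 in the low batch. The high batch held WT 4 and Blimp1-flox 3, the outlying libraries, so these contrasts cannot be assigned to the pancreas level. The 62 changed genes had a median log2 fold change of 1.10 in size in the high batch and 1.22 in the low batch. All 62 kept their sign in both, which was set in advance because their groups did not overlap. With the batch as a term edgeR called 391 genes, and 342 with Blimp1-flox 1 placed in the high batch.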

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

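The tests of passenger DNA, of B cell RNA, of the share of Foxp3-expressing cells and of the length trend by part were chosen after results bearing on them were seen. The tests of other splits, of the length trend over 3 lists and of WT 4 for those lists were set before. Of 94 groups of 4 libraries examined, 5 held 1 library far from the other 3, and chance gives about 4.7.

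In WT 4, Neb stood at 45.7 CPM against 14.3 to 16.5 in the other WT libraries, and Socs2 at 10.6 CPM against 4.80 to 5.44. In WT 2, Il4ra stood at 149 CPM against 131 to 132. The 1 WT count of Mmp25 was in WT 1 (0.0404 CPM). In Blimp1-flox 1, the library with the fewest counts, the 50 most abundant genes took 11.7% of counts, against 10.98% to 11.10% in the other Blimp1-flox libraries.

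The first pattern is the 62 changed genes. Only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes. This is the smallest share that 35 splits can give, so chance is unlikely but is not excluded. The highest other split, with 7, was the single other one with any. It followed the pancreas transcript batches, whose term in the real comparison gave 391 genes. Besides Prdm1, 1 of 61 changed genes, Mettl24, lay within 20 Mb of Prdm1 (1.64%, exact 95% interval up to 8.80%), against 1.07% of tested genes. This argues against most of the others being genes carried in strain DNA near the floxed allele, and leaves Mettl24 open. An effect of such DNA on genes elsewhere cannot be seen from gene positions. For B cell RNA, the median log2 fold change of the 29 lower genes other than Prdm1 was -0.86 without WT 4 and -0.96 with it. The B cell list itself kept a median of -1.87 without WT 4, so this value cannot decide. The excess of the 29 genes in WT 4 was 1.601 times that in WT 1 and WT 2 (median), against 16.8 times for B cell genes. Calls favour genes with even WT libraries, and none of 21 B cell genes was called, so a low ratio was partly set by the choice of genes. The excess of the 29 genes in WT 4 was smaller than that of the B cell genes, but its lower quartile was still 1.19 times. Most of the 29 genes were thus also higher in WT 4 than in WT 1 and WT 2, more weakly. A part from B cell RNA is not excluded. Adding a B cell score ended every call, with Prdm1 at -1.47 ± 0.44 (SE) after and -2.14 ± 0.31 before and smaller folds for 20 of 29 called named genes, in a fit where the score shared 62.6% of its variance with genotype, so a cell state that moves with the score stays open.

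The second pattern is the lower Treg core genes. A lower share of Foxp3-expressing cells would lower Foxp3 by as much, and the 95% intervals of all 4 called genes lay below that of Foxp3 (-0.65 to -0.15). These 4 were taken because they were called among 18 members, so part of this gap follows from that choice. With the B cell score as a covariate Foxp3 stood at -0.71 (-1.06 to -0.36) and 0 of the 4 intervals lay below it. Foxp3 counts are also uncertain because its exons overlap other genes, so this share stays open. The Foxp3-YFP+ CXCR5+ PD1+ sort selects against Foxp3-negative cells. Its purity was not given in the sources used here, and B cell transcripts were counted in the libraries. For the smaller shifts of the other genes, Ikzf2, Ikzf4, Nrp1 and Lrrc32 averaged 0.25 ± 0.14 (SE) above Foxp3 on the log2 scale, under 2 standard errors, and such a share cannot be told apart from a change within cells because the SE of Foxp3 alone was 0.13. An effect of genotype within the cells is likewise open.

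The third pattern is the higher glycolysis, oxidative phosphorylation and ribosomal protein lists. Fold changes went with gene length across 12363 genes, which are not independent replicates (Spearman rho = -0.22). The test set beforehand asked whether all 3 lists or none passed without the length trend, and 2 of 3 passed, which decides nothing for the 3 together. Divided after that was seen, glycolysis and oxidative phosphorylation both passed (2 of 2, medians 0.38 and 0.14), against the trend as their whole cause, while the ribosomal median went from 0.14 to 0.036 (camera adjusted p = 0.192), consistent with a length effect. All 3 of 3 passed without WT 4, but none passed with an estimated correlation, so the biological reading of the lists is open.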

How the results depend on the processing

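The fits without WT 4 and Blimp1-flox 3 together, with a B cell score, with a batch term and without the length trend were chosen after the data were seen. The main count of 62 changed genes came to 62 to 64 with other scalings, 64 with the stricter filter and 93 with no filter. It was 457 in DESeq2 (201 higher, 256 lower), 494 in limma-voom with quality weights (213 higher, 281 lower), 182 at an adjusted p under 0.10 and 38 with a log2 fold change of at least 1 in size. It was 157 without WT 4 and Blimp1-flox 3, the libraries farthest out on the first and second principal components, 391 with the batch term, 342 with Blimp1-flox 1 in the other batch and 0 with the B cell score, where of 29 called named genes 28 had a larger standard error and 20 a smaller fold. The other causes were not tested. Leaving out 1 library gave 20 (Blimp1-flox 1) to 127 (WT 1), with 27 without WT 2, 94 without Blimp1-flox 3 and 23 without Blimp1-flox 4. Prdm1 stayed lower in every alternative, from -1.95 to -2.36 with 1 library left out. It missed the threshold without Blimp1-flox 1 (-2.21, adjusted p = 0.103), with no filter (-2.14, adjusted p = 0.0502) and with the B cell score (-1.47, adjusted p = 0.715); over all alternatives its adjusted p ran from 6.6e-13 to 0.715. The 16 lists passing became 1 with an estimated correlation and 7 with fry, 13 to 18 with 1 library left out, and 12 with the B cell score. The 7 with fry were Treg core, TH1, TH17, cytokine, cytokine receptor and JAK-STAT, NF-kB and TNF receptor, and interferon-stimulated. Lists that passed camera but not fry were TFH and follicular, cytotoxic granule, cell cycle, glycolysis, oxidative phosphorylation, immediate early, heat shock, ribosomal protein, B cell and plasma cell.

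Replicate numbers did not pair the libraries: same-numbered libraries had correlations of deviations of 0.10, 0.15, -0.10 and -0.11. With a replicate block 52 genes were called (29 higher, 23 lower), 37 of them among the 62, Prdm1 stood at -2.13 and 15 lists passed, the cytotoxic granule list not among them (adjusted p = 0.0729). Among named genes, 29 were called, all 29 kept their sign in every alternative and 11 kept their call in all 8 fits without 1 library. Of 798 values of named genes under alternatives, 679 kept direction and side of the threshold, 114 lost and 3 gained a call, and 2 changed sign. Those were Gata3 in limma-voom (0.0024) and Cxcr5 with the B cell score (-0.0501), neither of them called. Of 638 list values, 583 kept direction and side, 48 lost and 6 gained a call, and the B cell list changed sign with the B cell score built from it (adjusted p = 0.376). Removing receptor segment, mitochondrial and haemoglobin genes took out 1 tested gene and so tests nothing. At this depth and spread per gene, simulated 1.5-fold changes were recovered in 40.2% of cases, so many changes of that size would be missed. The simulated genes varied independently, without outlying libraries or RNA of other cells, so the share in the real data may differ.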

Other observations

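The test on TH17 cytokine transcripts was chosen after their values were seen. These transcripts lay below the count filter. Il22, which encodes a cytokine of barrier tissues, had 4, 1, 0 and 4 counts in the WT libraries and 33, 8, 17 and 56 in the Blimp1-flox libraries. Il17a had 1 count over the WT libraries and 19 over the Blimp1-flox libraries, and Il17f had 0 and 19. By exact two-sided permutation tests of CPM the p for Il22 was 0.0286, the smallest that 4 against 4 libraries can give, and 0.0857 after adjustment over the 3 genes. For Il17a and Il17f the p was 0.143, also after adjustment, and both had 0 counts in Blimp1-flox 3.

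Mettl24, 1 of the 62 changed genes, lay at 40.7 Mb on chromosome 10, near Prdm1. It held 0.081, 0, 0 and 0.075 CPM in WT and 2.86, 1.04, 0.935 and 2.39 CPM in Blimp1-flox (edgeR adjusted p = 0.0082). It was chosen after its values were seen.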
